A study of Mus musculus with 12 samples.

How the data were processed

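Reduced representation bisulfite libraries were made from B cells sorted by division from 2 host mice, per the labels, with digestion by MspI and TaqI, size selection, bisulfite conversion and PCR, and sequenced as single-end reads. The deposited table used for the tests gives, for 760348 CpGs, the methylated and unmethylated read counts of each of the 12 samples, per the file headers. A second deposited table covers 1639598 CpGs, of which 879250 are outside the first, and was used only where the text says so. The same tables give the methylation of each CpG as a fraction, per the file headers, which equalled methylated reads over all reads to within 5.6e-16. Reads had been aligned to mm9 with Bismark and Bowtie2, per the submitters' processing notes, and versions of the aligners are not given in the sources used here. The first table held at least 10 reads in every sample at each CpG and listed each CpG once, so strands had already been joined. Nearest genes, distances to transcription start sites and annotation classes (promoter, from 2500 bp upstream to 500 bp downstream of the start site, 5′ UTR, exon, intron, 3′ UTR, intergenic) are those of the files, in mm9 coordinates, and a symbol was missing for 65092 of the 760348 CpGs. The symbol is that of the nearest transcript and the distance that to the nearest start site, which belonged to another gene at 62245 of the 568202 CpGs with a symbol within 50 kb of a start site and to no listed gene at 16967. A class can be that of an overlapping gene. The order of neighbouring genes was taken from a RefSeq gene table of another build (GRCm38), whose coordinates were not used.

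Replicates were separate host animals, and fractions with the same host number came from the same animal per the labels. Deviations of the 2 hosts from the fraction means, compared between fractions over 182714 CpGs, had correlations between -0.0025 and 0.0109 over the 15 pairs of fractions. Coverage differed between all libraries by more than counting noise (smallest chi-square per degree of freedom 1.20), so no library was counted as a copy of another. The libraries were amplified by PCR without molecular identifiers, so reads are not independent molecules and a read count understates the error of a single level. The dispersion estimated between hosts was therefore used in the tests, at 1.16 times binomial variation. At the 1192 CpGs with a median coverage of at least 150 reads the median dispersion was 1.40, so tests there rest on too little variation.

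Each CpG was tested with a quasi-binomial logistic model of its methylated and unmethylated reads with the fraction as the term, over all 12 samples. The dispersion was moderated across CpGs with squeezeVar of limma 3.58.1, which returned infinite prior degrees of freedom and so the same value for all CpGs, and was never taken below 1. A CpG is lower or higher where the Benjamini-Hochberg adjusted p was under 0.05 and the means differed by at least 20 points. The trend used the division number (0, 1, 3, 5, 8) over the 10 samples other than Div8pos, with the same limits on the fitted difference. Its residual degrees of freedom, and those of the models with a host term, were counted over libraries whose fitted level was neither 0 nor 1, a way of counting set after first fits had been seen. A gene's level was the mean percent methylation of the CpGs assigned to it within 50 kb of the nearest start site, of whichever gene, for the 16505 genes with at least 5 such CpGs, tested with limma (adjusted p under 0.05 and at least 10 points). Regions were runs of at least 3 CpGs that passed in the same direction, at most 500 bp apart. A region is given with the number of CpGs that passed. Its level is the mean over all covered CpGs between its ends, including those that did not pass. CpGs lower in 1 host were chosen with Fisher's exact test on the reads of that host, with the same limits, and followed in the other host. The mean level was tested by exact permutation of fraction labels within hosts. Odds ratios of annotation classes were calculated among CpGs with at least 20% methylation in the reference fraction, which could have fallen by 20 points.

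The gene lists (plasma cell, B cell identity, unfolded protein response and secretion, cell cycle, Toll-like receptor and NF-kB, DNA methylation machinery, migration, T cell, myeloid, NK cell, erythroid, imprinted and germline), the tests, the limits, the alternative settings and the rule for named genes were chosen before the data were examined. Each list's mean difference was compared with 10000 random lists of genes matched on CpG number and Div0 methylation, two-sided, with p adjusted over the 13 lists. The rule named, for Div8pos against Div0, Div8neg against Div0 and Div8pos against Div8neg, the 10 lower and 10 higher genes with the largest differences among those that passed and moved the same way in both hosts, the 5 regions with the most CpGs, and the plasma cell and B cell identity genes that passed or held at least 3 CpGs that passed. It also named the 5 lower and 5 higher genes of each early comparison, the 10 genes with the most trend CpGs and the 2 members of every list with the largest difference at Div8pos. Other regions, among them all higher ones, the one between Atg5 and Prdm1 and the chromosome 8 block, were chosen after their values were seen. Some genes that the rule named are not reported here.

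Alternatives were a coverage minimum of 20 reads, a limit of 10 points, a host term (block), Fisher's exact test on pooled reads, edgeR 4.0.16 (quasi-likelihood test with sample effects), no lower bound on the dispersion, each library left out in turn, summed reads for the mean level, autosomes alone, other gene and region definitions, other matching of random lists, and each host alone. The dispersion of each CpG alone, reads thinned at random to the total of the shallowest library, regions without host-dependent runs, the mean level without Div3 of host 196, and gene levels from CpGs whose nearest start site is the gene's own were added after the data had been seen. Simulated data had the coverage of these libraries (40000 CpGs, Div8pos against Div0). There the test found 40 of 200 drops of 20 points, 125 of 200 drops of 30 and 170 of 200 drops of 40. Of 39400 unchanged CpGs, 4 passed. Drops close to the limit were thus mostly missed in the simulation. It changed a smaller share of CpGs than passed in the data, which makes the adjusted p stricter. A true drop of 20 points can also miss the size limit itself. The shares found need not hold for the data. Calculations used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1 and Numba 0.67.0, R 4.3.3 for limma and edgeR, and Matplotlib 3.10.9 for the figures. RNA measurements of the same cells were not analysed here.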

Results

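DNA methylation was measured in mouse B cells sorted by the number of times they had divided in vivo. Naive splenic B cells (B220-positive, CD43-negative) carried a dye that is diluted at each division and were placed in 2 μMT hosts, mice of a strain that lacks mature B cells. They were stimulated in the host with lipopolysaccharide (LPS), a bacterial ligand that drives B cells to divide and to form antibody-secreting plasma cells. On day 3 after LPS, 6 fractions were sorted from each host: undivided cells (Div0), cells after 1, 3 and 5 divisions (Div1, Div3, Div5), and cells after 8 or more divisions without CD138 (Div8neg) or with CD138 (Div8pos), the surface marker of plasmablasts and plasma cells. This gave 12 samples, 2 per fraction, from the hosts numbered 196 and 197. Reduced representation bisulfite sequencing, which reads CpG-rich restriction fragments, gave methylated and unmethylated read counts at 760348 CpGs covered by at least 10 reads in all 12 samples. Read counts summed over these CpGs lay between 17969105 and 56775157 per library. A read that covers several CpGs counts once for each of them. The median coverage per CpG was 20, 23, 55, 23, 22 and 30 reads in host 196 and 52, 66, 62, 57, 41 and 55 reads in host 197, in the order Div0, Div1, Div3, Div5, Div8neg and Div8pos. Host 197 was the more deeply sequenced in every fraction, by the least at Div3, and its libraries carried more of the weight in tests on read counts. Below, a CpG or gene is said to be lower or higher only where it passed the test and the size limit given in the description of the processing.

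The first question was how the mean methylation level moved with division. The mean over all CpGs was 56.0% ± 0.215 at Div0, 55.8% ± 0.165 at Div1, 55.7% ± 0.274 at Div3, 55.2% ± 0.291 at Div5, 53.2% ± 0.0442 at Div8neg and 49.9% ± 0.422 at Div8pos (SD, n = 2 hosts each). Within hosts, the difference from Div0 was -0.203 points at Div1 (SD 0.0497), -0.324 at Div3 (SD 0.0589), -0.790 at Div5 (SD 0.0763), -2.86 at Div8neg (SD 0.171) and -6.11 at Div8pos (SD 0.207). Div8pos differed from Div8neg by -3.25 points (SD 0.378). Both hosts showed the same direction in each of these comparisons. CpGs with at least 80% methylation made up 52.3% of all CpGs at Div0, 51.2% at Div5, 47.3% at Div8neg and 40.4% at Div8pos. Between Div0 and Div8pos, CpGs between 20 and 80% went from 9.16% to 20.1% of all CpGs and those under 20% from 38.6% to 39.5%. The slope over the 6 ordered fractions gave a two-sided exact permutation p of 3.9e-06, the smallest that the 518400 arrangements of labels within hosts can give. Over the 5 fractions other than Div8pos the exact permutation p was 0.00014, again the smallest possible with 14400 arrangements. With 2 samples against 2 a single pair of fractions cannot go below an exact p of 0.3333, so pairs are given as differences with their SD. Calculated from summed reads instead of the mean over CpGs, the differences from Div0 were -2.75 points at Div1, -2.93 at Div3 and -2.35 at Div5. By summed reads the level at Div1, Div3 and Div5 was 52.8%, 53.3% and 53.7% in host 197. In host 196 it was 54.0%, 53.1% and 53.8%. The size and the order of the early differences thus depended on how CpGs were weighted.

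**Figure D1:**
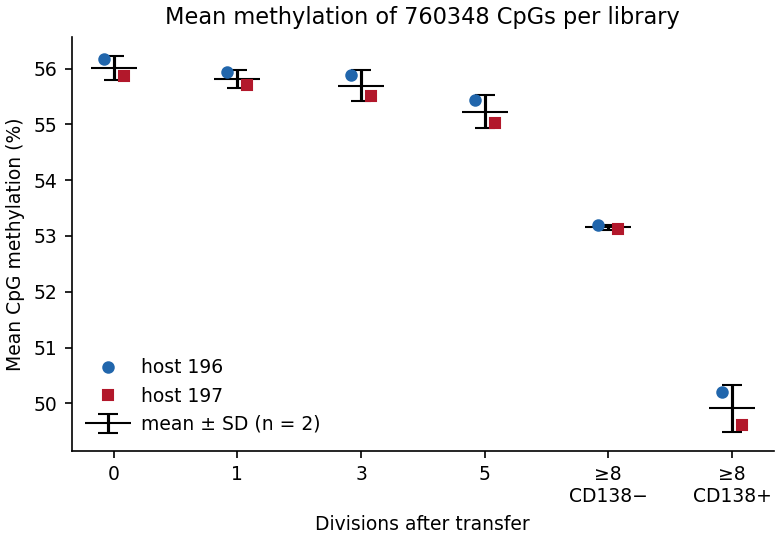
Mean CpG methylation in percent (vertical axis) of the 6 sorted fractions (horizontal axis), with 1 point per host and the mean of the 2 hosts with its SD. The level lay at 56.0% at Div0, 53.2% at Div8neg and 49.9% at Div8pos.

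Div8pos against Div0 compared CD138-positive cells with undivided cells. Methylation was lower at Div8pos at 50284 CpGs (6.61% of those tested) and higher at 206, with a median difference of -26.6 points at the lower CpGs, which went from a median of 92.5% to 63.4%. The largest gene-level loss was at Apobec1, a cytidine deaminase that edits messenger RNA. Its 5 CpGs (chromosome 6, 122541189 to 122541517, mm9) went from 92.0% ± 2.31 at Div0 to 21.5% ± 0.916 at Div8pos (SD, n = 2) and fell by 70.5 points (SE 1.90, limma adjusted p = 3.58e-07). Ndufb10, a subunit of mitochondrial respiratory complex I, fell by 63.8 points (SE 2.49) from 73.1% ± 1.54 to 9.23% ± 0.705. Gimap4, a lymphocyte GTPase, fell by 59.3 (SE 2.25) from 64.5% ± 1.89 to 5.2% ± 1.36, and both genes had a limma adjusted p of 9.27e-07. C1qbp, a mitochondrial matrix protein, fell by 54.0 points from 95.5% ± 2.37 to 41.5% ± 5.49, and Rab30, a small GTPase of the Golgi, fell by 45.3 from 92.3% ± 2.54 to 47.0% ± 0.878. Cyp8b1, Sp110, Susd3 and Myadm followed, and Calr4, the last of the 10 genes with the largest losses, fell by 37.7 points. In all, 2594 of 16505 genes (15.7%) were lower and 0 higher by limma, with 13485 genes at an unadjusted p under 0.05. Without the limit of 10 points, 13268 genes fell and 22 rose at a limma adjusted p under 0.05, so the size limit set these counts.

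Genes of the plasma cell programme and of B cell identity both lost methylation at Div8pos. Of 29 measured plasma cell genes, 11 were lower, and the list's mean difference was -8.12 points against -5.58 in random lists matched on CpG number and Div0 level (permutation p adjusted over 13 lists = 0.0026). Prdm1, the transcription factor that commits cells to the plasma cell fate, fell by 14.4 points (SE 0.843) over 74 CpGs from 62.0% ± 0.562 to 47.6% ± 1.19. Irf4, which acts with it, fell by 12.1 (SE 0.970) from 21.1% ± 1.41 to 9.05% ± 0.317. Il10, a cytokine made by activated B cells and plasma cells, fell by 30.1 points (SE 1.39) from 71.8% ± 0.582 to 41.7% ± 1.98. The survival receptor gene Tnfrsf17 fell by 10.8 (SE 1.51) from 59.2% ± 0.895 to 48.4% ± 2.26. The other lower plasma cell genes were Tnfrsf13b, Ly6a, Zbtb20, Txndc5, Sub1, Slamf7 and Creld2. Sdc1, which encodes CD138 itself, lay at 48.0% ± 0.926 and 42.3% ± 0.272, a difference under the limit of 10 points. Mzb1 (19.3% and 9.40%), Herpud1, Derl3 and Cacna1h were under that limit too. Cd93, a member of this list too, had the other sign, at 15.3% ± 0.103 and 23.8% ± 0.354 (limma adjusted p = 0.000580, 3 higher CpGs and 1 lower), with a difference of 8.50 points, under the limit. Of 26 measured B cell identity genes, 11 were lower, and the list's mean difference of -9.95 points lay beyond the -6.15 of matched random lists (adjusted permutation p = 0.0013). Blk, a kinase of B cell receptor signalling, fell by 21.1 points from 89.3% ± 2.44 to 68.2% ± 1.04, and Fcrla fell by 20.1. The adaptor gene Blnk fell by 16.2 from 49.6% ± 1.75 to 33.4% ± 1.00 (limma adjusted p = 2.60e-06). Cd37, Pou2af1, Ms4a1, Pou2f2, Bank1, Cd22 and Ciita were lower too. Pax5, the factor that maintains B cell identity, was already low and lay at 19.2% ± 1.37 and 15.3% ± 0.489, and Ebf1, Foxo1, Bach2, Ets1, Irf8, Id3, Ikzf1, Ikzf3 and Tcf3 held at least 3 changed CpGs with a gene-level difference under 10 points.

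Toll-like receptor and NF-kB genes had 6 of 29 members lower (mean -8.42 points against -5.93, adjusted permutation p = 0.00364). They were led by Tlr6, which fell by 26.5 points, and the NF-kB inhibitor gene Nfkbie, which fell by 26.1. Migration genes had 6 of 16 lower (mean -8.90 against -5.75, adjusted permutation p = 0.00737). Cxcr5, the receptor for homing to B cell follicles, fell by 26.1 points from 59.5% ± 1.07 to 33.4% ± 0.615, and S1pr1, the receptor for lymphocyte egress, fell by 23.5 from 46.2% ± 2.40 to 22.7% ± 1.20. Imprinted genes lost less than matched lists (mean -4.86 against -7.05, adjusted permutation p = 0.0013), with 2 of 25 lower, Airn and Plagl1. Germline genes also lost less (mean -6.56 against -8.77, adjusted permutation p = 0.0026), with 4 of 23 lower, among them Piwil2 and Brdt. These 6 results depended on the measure. By the share of members with a lower CpG, 0 lists were apart at Div8pos, with adjusted permutation p of 0.299 for plasma cell, 0.383 for B cell identity, 1 for Toll-like receptor and NF-kB, 0.778 for migration, 0.383 for imprinted and 1 for germline genes. When random lists were matched on CpG number only, 3 lists were apart, and imprinted (adjusted permutation p 0.564), germline (0.684) and migration genes (0.0624) were not, the last also not within 5 kb of the start site (0.0542). The remaining lists did not pass the test against random lists. Of 27 genes of the unfolded protein response and secretion, 1 was lower, Spcs2 (adjusted permutation p of the list 0.0824). Of 31 cell cycle genes, 1 was lower, Mki67, which fell by 10.1 points, while Mcm6 was under the limit (adjusted permutation p 0.773). Of 24 genes of the DNA methylation machinery, 2 were lower, Zbtb38 among them (adjusted permutation p 0.705). Of the markers of other cells, 5 of 20 T cell genes were lower, Cd4 among them, and 7 of 20 myeloid genes, Itgax and Lyz2 among them (adjusted permutation p 0.932 and 0.705). So were 3 of 7 NK cell genes, with Il2rb and Prf1, and 1 of 9 erythroid genes, Slc4a1 (adjusted permutation p 0.405 and 0.773). Adjusted over the list alone, each of the 13 counts was the same.

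**Figure D2:**
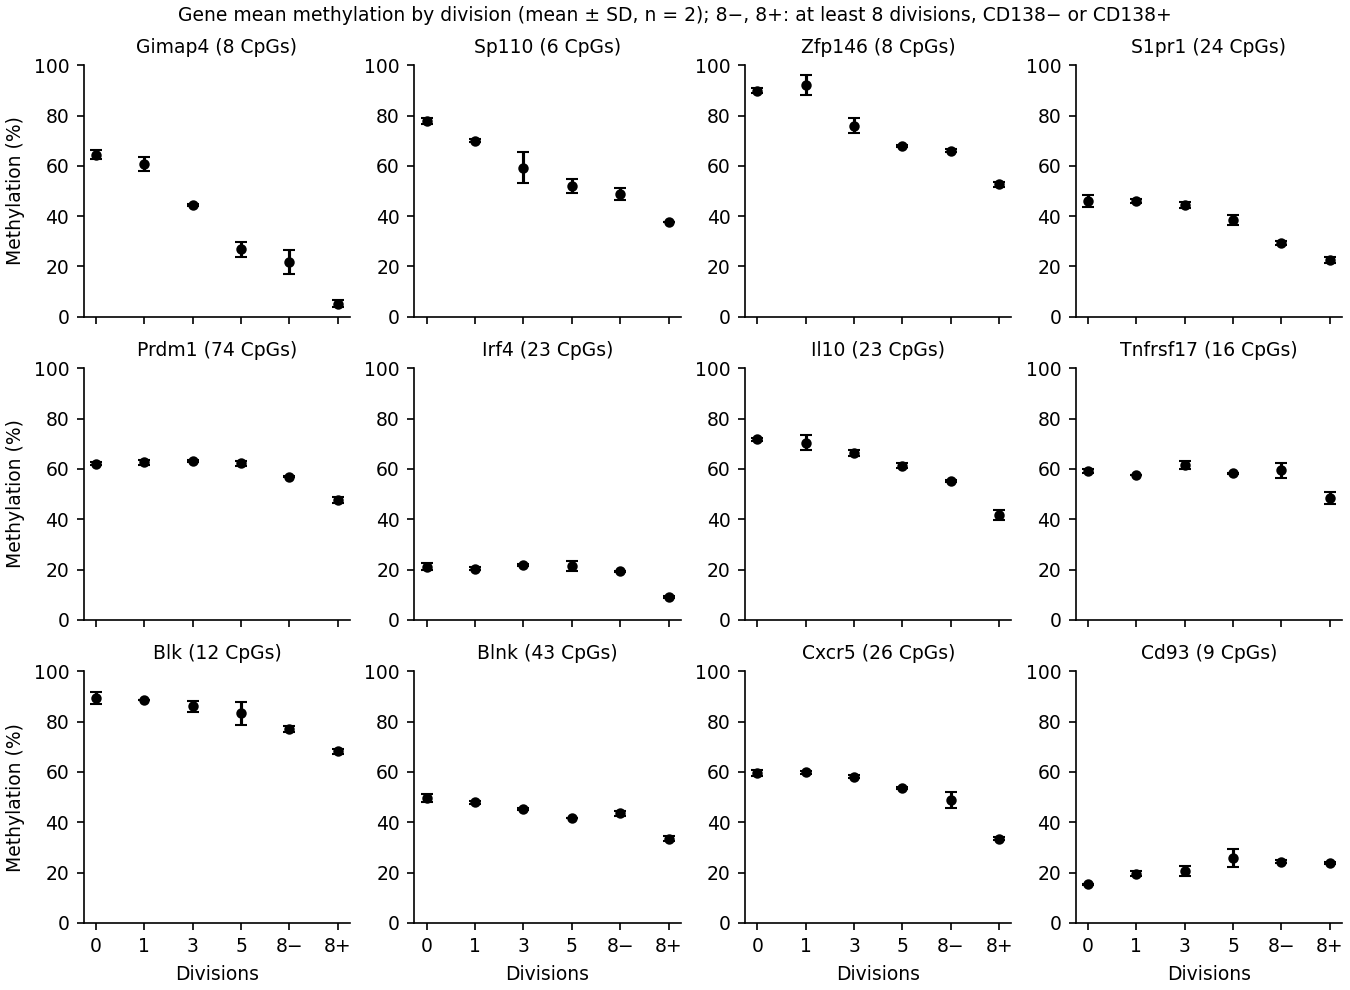
Gene-level methylation in percent (vertical axes) over the 6 fractions (horizontal axes) of 12 named genes, with points for the mean of the 2 hosts and bars for the SD. Gimap4, Sp110 and Zfp146 were lower than at Div0 at Div5, Div8neg and Div8pos, Prdm1 and Irf4 were lowest at Div8pos, and Cd93 lay at 15.3% at Div0 and 25.7% at Div5.

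Adjacent lower CpGs formed 2032 regions at Div8pos and adjacent higher CpGs formed 8. The most CpGs were in Cnp (chromosome 11, 100437385 to 100438056, 5′ UTR, exon and intron, 23 CpGs), which went from 85.2% ± 0.850 to 50.1% ± 2.65 with a median coverage of 43.5 reads, and in Runx3. This lymphocyte transcription factor gene (chromosome 4, 134710711 to 134712105, exon and intron, 23 CpGs) went from 88.1% ± 0.829 to 51.3% ± 7.0 at Div8neg and 36.4% ± 4.02 at Div8pos. The zinc finger gene Zfp710 (chromosome 7, 87230742 to 87231443, exon and intron, 18 CpGs) went from 92.2% ± 0.380 to 48.3% ± 4.80. Mid1 (chromosome X, 166417000 to 166417808, intron and the promoter of an overlapping gene, 16 CpGs) went from 67.8% ± 1.57 to 39.5% ± 3.03. An intergenic region (chromosome 8, 125952484 to 125953920, 22 CpGs) went from 95.6% ± 3.88 to 62.5% ± 41.1, with an SD that reflects a difference between the hosts. Among CpGs with at least 20% methylation at Div0, 12.1% of intronic and 6.52% of exonic CpGs were lower, with odds ratios against all other such CpGs of 1.25 for introns and 0.535 for exons. Promoter CpGs had an odds ratio of 1.25, which turned to 0.912 when the size limit was 10 points. The higher regions included an exon of Cd93 (chromosome 2, 148267284 to 148267493), which went from 10.8% ± 0.196 to 48.5% ± 5.55. An exon of the immediate early gene Egr3 (chromosome 14, 70479525 to 70479576) went from 19.5% ± 7.97 to 46.3% ± 6.54, and an intron of Nfatc2 (chromosome 2, 168379267 to 168379275) from 48.3% ± 2.79 to 71.8% ± 5.60, with 3 or 4 CpGs each. The number of lower CpGs was 14342 without Div0 of host 197 and 33129 without Div8pos of host 197, and the number of higher CpGs was 53 and of higher genes 1 without Div0 of host 197. With the dispersion of each CpG estimated from that CpG alone, 0 CpGs passed in this and in each of the other 5 comparisons, with 135573 at an unadjusted p under 0.05 here, and edgeR gave 35949 lower and 58 higher CpGs.

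**Figure D3:**
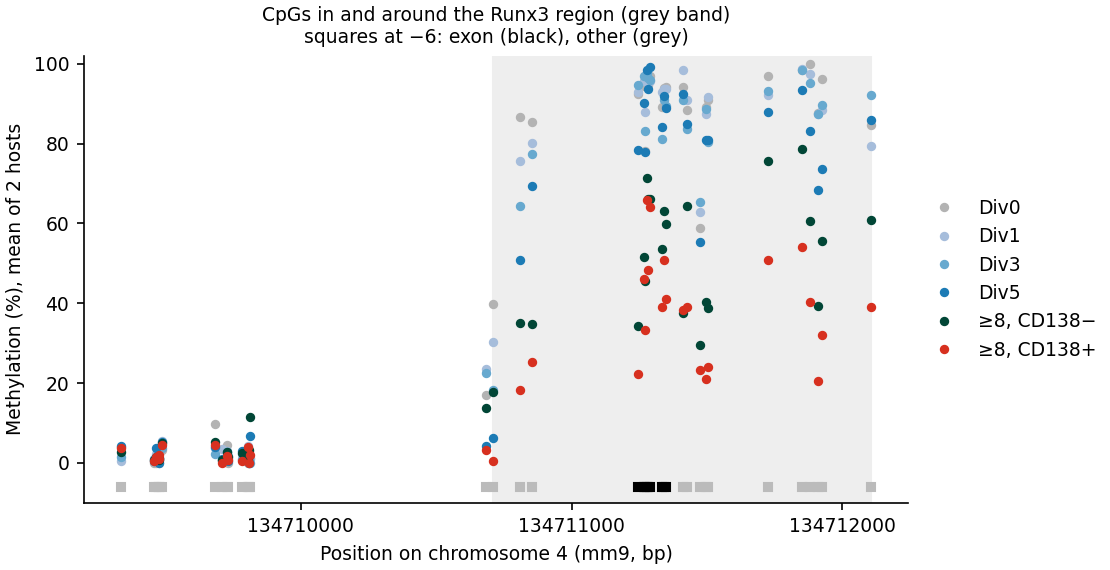
Methylation in percent (vertical axis) of each CpG in and around the Runx3 region against its position on chromosome 4 in mm9 (horizontal axis), as the mean of the 2 hosts for each of the 6 fractions, with the region shaded and squares marking exonic CpGs in black and other CpGs in grey. The region's mean was 88.1% at Div0, 78.9% at Div5, 51.3% at Div8neg and 36.4% at Div8pos.

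Div8neg against Div0 compared cells of 8 or more divisions that lacked CD138 with undivided cells. Ndufb10 fell by 43.8 points to 29.3% ± 3.03 (SE 2.49, limma adjusted p = 6.25e-05), and Gimap4 fell by 42.7 points to 21.8% ± 4.62 (SE 2.25, adjusted p = 5.56e-05). Cyp8b1, an enzyme of bile acid synthesis, fell by 31 from 93.3% to 62.2%, and Sp110, an interferon-inducible nuclear protein, fell by 29.0 from 77.7% to 48.7%. Rab30 fell by 26.2 points, and Pik3ip1, Zfp146, Rnf167 and Unc119 followed down to Gm8817, which fell by 22.5. At a limma adjusted p under 0.05 alone, 6874 genes fell and 47 rose. With the limit of 10 points, 246 genes were lower and 2 higher. The higher genes were Igll1, the surrogate light chain gene of B cell precursors, which went from 30.9% ± 4.52 to 42.7% ± 0.0856 (adjusted p = 0.00856), and Bckdha, which went from 47.4% ± 1.94 to 58.0% ± 0.768 (adjusted p = 0.00167). B cell identity genes lost more than matched random lists (mean -4.45 points against -2.80, adjusted permutation p = 0.0182), with 2 of 26 lower, Blk, which fell by 12.2 points, and Cd37, which fell by 10.2. So did the Toll-like receptor and NF-kB genes (mean -4.47 against -2.70, adjusted permutation p = 0.0104), with 3 of 29 lower, Tlr6 among them. In host 196 alone the B cell identity list was not apart (adjusted permutation p 0.211), and by the share of members with a lower CpG 6 lists were apart. Of the plasma cell genes, 2 of 29 were lower. Il10 fell by 16.6 points and Tnfrsf13b fell by 12.3, and the list's mean did not pass the test against matched lists (adjusted permutation p = 0.0728). Prdm1 lay at 57.0% ± 0.283 and Irf4 at 19.4% ± 0.198, under the limit of 10 points. Of the migration genes, S1pr1 fell by 16.9 points and Cxcr5 fell by 10.7.

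At single CpGs, 5935 were lower at Div8neg than at Div0 and 302 higher, with a median difference of -30.3 points at the lower CpGs. They formed 343 lower and 11 higher regions. Runx3 (chromosome 4, 134710809 to 134711923, 20 CpGs) went from 90.6% ± 1.72 to 52.5% ± 6.54, and a region assigned to Arhgef11 (chromosome 3, 87405100 to 87405359, intergenic, 12 CpGs) from 90.9% ± 2.06 to 29.2% ± 0.627. Zfp710 (12 of 16 covered CpGs) went from 92.0% ± 0.357 to 56.9% ± 0.945, and an intron of Rassf3 (chromosome 10, 120872630 to 120872834, 10 CpGs) from 70.1% ± 5.72 to 31.4% ± 6.96. The region with the most CpGs, 22, was again the intergenic one on chromosome 8 where the hosts differed. The lower count was 1046 without Div0 and 1821 without Div8neg of host 197, and the higher count 200 without Div0 of host 196, 24 without Div0 of host 197 and 76 without Div8neg of host 197, which also took the higher genes to 5. edgeR gave 2329 lower and 75 higher CpGs.

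Div8pos against Div8neg compared cells of the same division class with and without CD138. That class has no upper limit, and the numbers of divisions within it are not given for either fraction. Differences that go with CD138 therefore cannot be told apart here from differences that go with further divisions. Apobec1 was lower in the CD138-positive cells, at 21.5% ± 0.916 against 73.4% ± 3.61 (it fell by 51.9 points, SE 1.90, limma adjusted p = 8.84e-06). C1qbp fell by 33.5 points and Myadm, a myeloid-associated membrane protein gene, fell by 30.9 from 68.2% ± 1.18 to 37.4% ± 2.16. Atp2b3, a calcium pump of the plasma membrane, fell by 29.3 points from 94.6% ± 2.75 to 65.3% ± 0.216, and Man1b1, a mannosidase of the secretory pathway, fell by 27.0 from 59.0% ± 0.327 to 32.0% ± 4.23. Calr4, Gm1604b, 2010109I03Rik, Gpnmb and Crybb1, which followed, fell by 21.6 points or more. Of the plasma cell genes, 3 of 29 were lower. Il10 fell by 13.6 points, Tnfrsf17 fell by 10.9 and Irf4 fell by 10.4, and the list lost more than matched random lists (mean -4.57 points against -3.0, adjusted permutation p = 0.0052). Prdm1 had a difference of -9.34 points (adjusted p = 0.000214), just under the limit. B cell identity genes lost more as well (mean -5.50 against -3.34, adjusted permutation p = 0.00693), with 5 of 26 lower. Pou2af1, a co-activator of immunoglobulin transcription, fell by 16.4 points and Ms4a1, which encodes CD20, fell by 14.3. Fcrla fell by 11.1 and Blnk fell by 10.1. Migration genes lost more (mean -5.05 against -3.12, adjusted permutation p = 0.0123), with Cxcr5, which fell by 15.4 points, as the 1 lower gene. Imprinted genes lost less (mean -2.37 against -3.75, adjusted permutation p = 0.0052, with 0 of 25 lower). Matched on CpG number only, migration (adjusted permutation p 0.0715) and imprinted genes (0.325) were no longer apart. Nor were migration genes within 5 kb of the start site (0.314) or in host 196 alone (0.211), and imprinted genes by the share of members with a lower CpG (1). Over all genes, 8953 fell and 22 rose at a limma adjusted p under 0.05 alone. With the limit of 10 points, 345 were lower and 1 higher, the odorant receptor gene Olfr1184 (80.9% ± 7.24 to 91.3% ± 2.37), which lay at 94.6% ± 0.636 at Div0, above both. On the logit scale, with at least 10 CpGs per gene and within 5 kb of the start site, 0 genes were higher.

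At single CpGs, 4833 were lower in Div8pos than in Div8neg and 53 higher, in 209 lower regions and 0 higher regions. An intron of the transferrin gene Trf (chromosome 9, 103115172 to 103115354, 11 CpGs) went from 80.05% ± 1.34 to 51.9% ± 2.63, and Crybb1 (chromosome 5, 112698365 to 112698804, exon and 3′ UTR, 9 CpGs) from 56.7% ± 4.64 to 10.5% ± 0.857. Csrnp1 (chromosome 9, 119882619 to 119882921, 9 of 14 covered CpGs) went from 72.9% ± 5.94 to 49.1% ± 0.0144 and an intron of St3gal2 (chromosome 8, 113475081 to 113475324, 7 CpGs) from 49.8% ± 2.26 to 13.7% ± 1.66. Of several regions with 6 CpGs, an intergenic one between Atg5 and Prdm1 (chromosome 10, 44120496 to 44120755) went from 94.4% ± 2.36 at Div0 and 56.8% ± 0.661 at Div8neg to 4.29% ± 1.05 at Div8pos. The lower count was 2359 without Div8neg of host 196, 832 without Div8neg and 1127 without Div8pos of host 197, and the higher count 11 without Div8neg of host 197. Without that library 6 genes were higher, and 2 without Div8pos of host 197, while edgeR gave 1116 lower and 2 higher CpGs.

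The early fractions were compared with Div0 to see which changes preceded the late divisions. At Div5, Gimap4 fell by 37.7 points from 64.5% ± 1.89 to 26.8% ± 3.00 (SE 2.25, limma adjusted p = 0.000673). Sp110 fell by 25.8 points to 51.9% ± 2.71 and Zfp146 fell by 22 to 67.9% ± 0.236. Pik3ip1, an inhibitor of phosphoinositide kinase signalling, fell by 17.5 to 39.2% ± 0.950, and Mlxip, a glucose-responsive transcription factor, fell by 17.2 to 81.3% ± 3.14 (adjusted p = 0.0127). In all, 17 genes were lower and 1 higher, Cd93, a receptor of early B cells and plasma cells, which rose by 10.4 points from 15.3% ± 0.103 to 25.7% ± 3.53 (adjusted p = 0.0225). Il10 was among the lower genes and fell by 10.5 points. Without the limit of 10 points, 77 genes fell and 2 rose at a limma adjusted p under 0.05. B cell identity genes as a list lost more than matched random lists at Div5 (mean -2.39 points against -0.774, adjusted permutation p = 0.0026) and at Div3 (mean -1.20 against -0.316, adjusted permutation p = 0.0286). So did the Toll-like receptor and NF-kB genes at Div5 (mean -1.93 against -0.743, adjusted permutation p = 0.0052) and at Div3 (mean -0.911 against -0.304, adjusted permutation p = 0.0494). No member of either list was lower at gene level by limma. No alternative setting was run for the lists at Div3 and Div5. At single CpGs, 936 were lower and 42 higher at Div5 and 205 lower and 9 higher at Div3, with median differences of -38.5 and -37.2 points at the lower CpGs. At Div1, 0 CpGs were lower or higher by the quasi-binomial test (41343 at an unadjusted p under 0.05), 0 by edgeR (22197) and 0 with each CpG's own dispersion (8034). The 41343 were 5.44% of the CpGs tested. In the simulated data, 6.40% of CpGs unchanged at Div1 had an unadjusted p under 0.05 by that test, so the 41343 are no sign of change. limma gave 0 genes at Div1 (558 of 16505 at an unadjusted p under 0.05) and 0 at Div3 (630 of 16505). At Div5 the lower count was 319 without Div0 and 273 without Div5 of host 197, and the higher count 24 without Div0 of host 196, 15 without Div0 of host 197 and 5 without Div5 of host 197. At Div3 the lower count was 135 without Div0 of host 196, 40 without Div0 of host 197 and 105 without Div3 of host 197 and 141 without Div3 of host 196, a library whose depth and chromosome 8 block were close to those of host 197, so that a mix-up at Div3 was not excluded. There the higher count was 2 without Div0 of host 197, and edgeR gave 76 lower CpGs at Div3 and 517 at Div5.

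Change with division number was fitted over Div0, Div1, Div3, Div5 and Div8neg, without Div8pos. By this single slope, methylation fell with division number at 7703 CpGs (1.01%) and rose at 343. A CpG that changed at Div8neg alone can also pass, so these counts do not separate a gradual change from a late one. The genes with the most falling CpGs were Foxp1, a transcription factor of B cell development, with 27 of 239, Runx3 with 24 of 178, Rassf3 with 23 of 154, Mid1 with 20 of 226, and Dtx1, a regulator of Notch signalling, with 18 of 107. Zmiz1 had 16, and Bmp2k, Camk2a, Pced1b and Pvt1 had 14 each. Foxp1 as a whole went from 51.7% ± 0.332 at Div0 to 47.5% ± 0.298 at Div5 and 45.4% ± 0.661 at Div8neg, and Dtx1 from 40.4% ± 0.246 to 33.5% ± 0.333 and 31% ± 0.142. Without Div8neg of host 197 the counts were 3624 and 179.

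The order of the losses was then followed in libraries that had taken no part in the choice of CpGs. The 5449 CpGs that were lower at Div8pos than Div0 in host 196 had mean levels in host 197 of 82.9% at Div0, 81.4% at Div1, 77.8% at Div3, 70.9% at Div5, 59.1% at Div8neg and 39.8% at Div8pos, and 99.4% of them differed in the same direction at Div8pos there, whether or not they passed the test. Of their total loss, 3.39% was present at Div1, 11.8% at Div3, 27.8% at Div5 and 55.1% at Div8neg. The 43757 CpGs chosen in host 197 went in host 196 through 86.5%, 85.8%, 84.7%, 82.2% and 74.8% to 62.8%, with 2.98%, 7.62%, 18.0% and 49.2% of the loss present at Div1, Div3, Div5 and Div8neg and 93.9% of them with a difference in the same direction at Div8pos. The number that passed in both hosts was 4389. Higher CpGs were less alike: of 29 chosen in host 196, 48.3% differed in the same direction at Div8pos in host 197, of 182 chosen in host 197, 63.7% did so in host 196, and 3 passed in both.

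**Figure D4:**
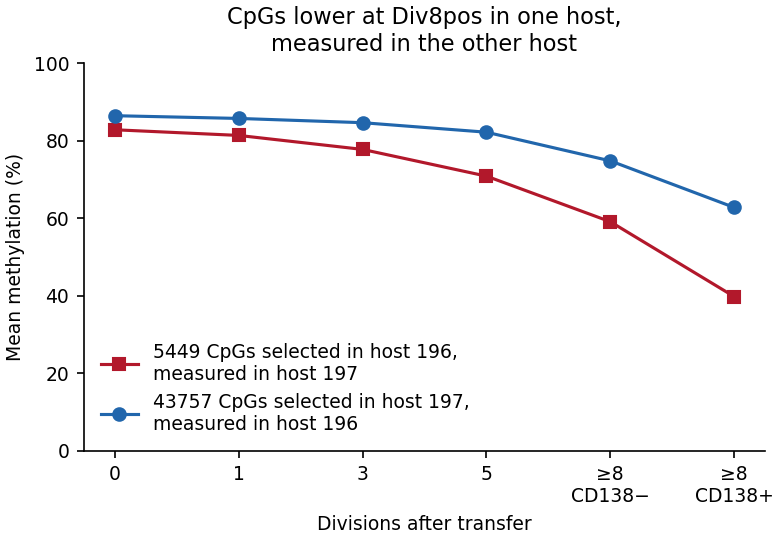
Mean methylation in percent (vertical axis) over the 6 fractions (horizontal axis) of CpGs chosen for lower methylation at Div8pos in one host and measured in the other. The CpGs chosen in host 196 fell in host 197 from 82.9% at Div0 to 39.8% at Div8pos, and those chosen in host 197 fell in host 196 from 86.5% to 62.8%.

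The hosts differed in an intergenic block on chromosome 8 (125951379 to 125955590, mm9, 72 CpGs), which contains the region named above. In host 197 its methylation was 93.1% at Div0, 88.2% at Div1, 76.1% at Div3, 54.2% at Div5, 42.9% at Div8neg and 34.9% at Div8pos. In host 196 it was 97.0%, 96.5%, 79.4%, 95.7%, 93.5% and 90.1% in the same order. Of 3 other runs of CpGs that differed between the hosts, 1 lay close by (125957893 to 125958020) and went from 92.9% at Div0 to 33.6% at Div8pos in host 197 and from 94.6% to 88.4% in host 196. An intron of AI506816 went from 93.6% to 58.9% and from 98.6% to 91.9%, and an exon of Eef1a1 from 16.5% to 8.08% and from 20.2% to 49.5%, in the same order of hosts. The coverage of the block relative to the median of the library rose in host 197 from 1.32 at Div0 to 3.67 at Div8pos, and was 1.23 and 1.69 in host 196. With 2 hosts, swapping the host labels within fractions gave an exact permutation p of 0.3125 for the difference in slope. The smallest possible value, 0.03125, requires the hosts to differ in opposite directions in the early and the late fractions. Host 197 was lower in every fraction, and swapping early fractions with small differences barely moves the slope. That test therefore could not decide whether the hosts diverged.

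**Figure D5:**
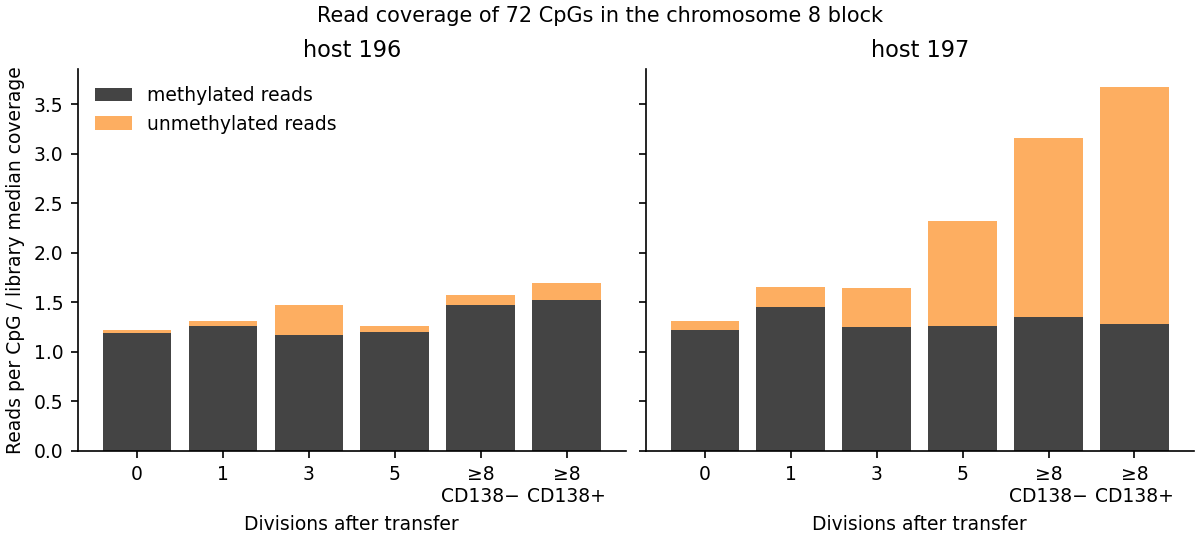
Reads per CpG over the library's median coverage (vertical axis), stacked as methylated and unmethylated reads, in the chromosome 8 block for the 6 fractions (horizontal axis) of each host. In host 197 the methylated part was 1.23 at Div0 and 1.28 at Div8pos, while the unmethylated part rose from 0.0909 to 2.39.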

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

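All tests in this part were chosen after the results they bear on had been seen.

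The trend of methylation with division number differed between the 2 hosts at 56 CpGs by a quasi-binomial host by division term (adjusted p under 0.05), with 52423 CpGs at an unadjusted p under 0.05. Of these, 14 lay on chromosome 17 between 39980818 and 39984443 with no gene symbol, 13 in an intron of Cmss1 (chromosome 16, 57391594 to 57391749), 6 in Jarid2, 4 in Gm8579, 3 in Ddx18 and 2 in the chromosome 8 block. The remaining 14 were single CpGs. Many of the 56 were covered far above the library medians, with a median of 1803 reads at position 39981449 of chromosome 17. The CpG assigned to Lrrc4c, with the lowest adjusted p, had a median of 11431 reads. The test used a dispersion of 1.14 for all CpGs, and tests at such coverage rest on too little variation. The Cmss1 CpGs were at 29.4%, with coverage 5.08 times the library median, at Div0 of host 196, at 72.6% and 1.36 times at Div8pos of host 196, and at 27.7% and 5.21 times at Div8neg of host 197.

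The chromosome 8 block lost methylation with division in host 197, with a slope of -12.8 points per fraction against -0.784 in host 196. The exact permutation p of that difference was 0.3125, from the test above, which could not decide it. Loss on the resident copies alone is argued against, since normalised coverage of the block at Div8pos of host 197 was 2.79 times that at Div0, beyond the middle 95% (up to 1.30) and the highest value (1.56) of 9985 random runs of as many CpGs. Depth is argued against too, since Div0 of host 197, a library as deep, lay 58.2 points above Div8pos. Normalised methylated reads stayed at 1.05 times their Div0 value, unmethylated reads reached 26.3 times and the flanks 10 to 50 kb from the block, beyond the neighbouring run, had a coverage ratio of 1.11, so a candidate explanation is that unmethylated copies of the sequence were added in the dividing cells of host 197, for example by a provirus, which is a hypothesis and was not tested against sequence. In host 196 unmethylated reads at Div8pos also rose, to 4.63 times Div0, but only from 0.0363 to 0.168 of the library median. Methylated reads there were 1.28 times Div0. The coverage ratio of the block in host 196, 1.38, lay inside the middle 95% of random runs (0.679 to 1.56). It stays open why Div3 of host 196, at 79.4%, lay close to Div3 of host 197, at 76.1%. Its median coverage of 55 reads was also nearer that of host 197 libraries than the 20 to 30 of the other host 196 libraries, and a mix-up of libraries at Div3 was not excluded, in which case the 2 samples at Div3 need not stand for 2 hosts.

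Reads aligned to the Y chromosome in all 12 libraries, which the labels give as female. Read counts were summed over the 465 Y chromosome CpGs outside the table used for the tests. The sum was 3425 in the library with the fewest and 10513 in the library with the most. Misaligned reads from X-linked relatives are argued against, since median coverage of X chromosome CpGs was at most 0.667 of that of autosomes in any library. A minor share of male cells is argued against, since coverage at Y-linked start sites was 1 to 1.68 times that at X-linked start sites. Start sites on the X chromosome were at most 1.87 points more methylated than those on autosomes, as would be seen with no inactive X chromosome, so the transferred cells may have come from male mice. Start sites of Ddx3y (3.10% over 16 CpGs) and Eif2s3y (4.97% over 8) were unmethylated while those of Usp9y (96.2% over 10) were methylated, and the sex of donors and hosts apart is not given in the sources used here.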

How the results depend on the processing

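The dispersion of each CpG alone, the thinned reads and a gene's own start site were chosen after seeing the data, and the other alternatives given here were planned. Of 551 alternative values, 398 kept their direction and side of the threshold or their size, 121 moved, 16 lost and 15 gained a call, and 1 reversed, the promoter odds ratio, at 0.912 with a limit of 10 points. The host term (replicate block) gave 194 lower CpGs at Div3, 887 at Div5, 5311 at Div8neg, 49086 at Div8pos and 4064 at Div8pos against Div8neg, 7653 in the trend and 2594, 245 and 344 lower genes, and changed no call of a named gene that had passed. Removing the lower bound on the dispersion left every count as it was. It could not do otherwise, since the single dispersion of 1.16 lay above that bound of 1, and these counts are among the 398. In pairs of lower and higher CpGs, in the order Div3, Div5, Div8neg, Div8pos and Div8pos against Div8neg, 20 reads gave 115 and 10, 443 and 31, 2244 and 150, 12210 and 71, and 2120 and 32, edgeR 76 and 2, 517 and 4, 2329 and 75, 35949 and 58, and 1116 and 2, and thinned reads 47 and 2, 434 and 8, 2684 and 106, 34832 and 149, and 1675 and 19. A limit of 10 points gave 1 lower CpG at Div1, 9114 and 564 at Div8neg, 111216 and 630 at Div8pos and 99 higher CpGs at Div8pos against Div8neg, and Fisher's exact test gave 1 lower CpG at Div1 and 20 higher at Div3. With each CpG's own dispersion all 6 comparisons had 0 lower and 0 higher CpGs, with 10161, 13650, 42817, 135573 and 38002 at an unadjusted p under 0.05 from Div3 on. The trend gave 2257 and 122 CpGs with 20 reads and 17529 and 969 with 10 points.

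Leaving out 1 library at a time, where the lone sample of a fraction is assumed to vary like the others, gave lower CpGs between 0 and 1 at Div1, 40 and 141 at Div3, 273 and 930 at Div5, 1046 and 5145 at Div8neg, 14342 and 52522 at Div8pos, 832 and 4008 at Div8pos against Div8neg and 3624 and 8405 in the trend. Higher CpGs lay between 0 and 1, 2 and 10, 5 and 32, 24 and 288, 53 and 213, 11 and 52, and 179 and 411 in that order, and higher genes between 0 and 1 at Div8pos, 2 and 5 at Div8neg and 1 and 6 at Div8pos against Div8neg. From Div3 on, the lowest counts of lower CpGs came without a host 197 library.

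For the mean level, summed reads gave differences from Div0 of -2.75, -2.93, -2.35, -5.80 and -8.49 points and -2.68 for Div8pos against Div8neg, and 20 reads gave -0.246, -0.648, -2.33 and -5.02 from Div3 on and -2.69. Regions of at least 5 CpGs numbered 352 lower and 0 higher at Div8pos, 82 and 1 at Div8neg and 43 lower at Div8pos against Div8neg. Genes within 5 kb of the start site gave 1036 lower and 2 higher at Div8pos, 144 lower at Div8neg and 205 lower and 0 higher at Div8pos against Div8neg, genes with at least 10 CpGs 118 and 1 at Div8neg and 137 and 0 at Div8pos against Div8neg, and the logit scale 0 higher there. Gene levels from CpGs whose nearest start site is the gene's own gave 2344, 241 and 343 lower and 0, 3 and 2 higher genes at Div8pos, Div8neg and Div8pos against Div8neg, with 6, 2 and 5 lists apart, germline genes being the one added (adjusted permutation p 0.0437). Lists apart from random lists numbered 3 in place of 6 at Div8pos and 2 in place of 4 at Div8pos against Div8neg when matched on CpG number only, when imprinted and germline genes were no longer apart (adjusted permutation p 0.564 and 0.684 at Div8pos), and 0 at Div8pos and 6 at Div8neg by the share of members with a lower CpG. At Div8neg they numbered 4 within 5 kb, 1 in host 196 alone and 4 in host 197 alone. The exon odds ratio was 0.608 with 10 points, and host 196 alone gave 1.5 for promoters, 0.639 for exons, 1.59 for introns, 0.731 for intergenic CpGs and 0.503 beyond 50 kb of a start site. CpGs chosen in host 197 had 2.98%, 7.62%, 18.0% and 49.2% of the loss at Div1, Div3, Div5 and Div8neg. Fewer CpGs or reads, or a lower limit, by construction change the counts with 20 reads, thinned reads, left-out libraries and 10 points; for the others the cause was not tested. Joining the 2 strands of a CpG was not run, since the table lists each CpG once.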

Other observations

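The tests on gene families and on the Div8neg gains in this part were chosen after the results were seen.

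The loss extended beyond the CpGs used for the comparisons. At 879250 further CpGs, which had fewer than 10 reads in at least 1 sample, the mean level went from 65.1% ± 0.215 at Div0 through 63.9% ± 0.325 at Div5 and 61.2% ± 0.138 at Div8neg to 56.9% ± 0.496 at Div8pos (SD, n = 2, over the 852532 with reads in all samples). There, 46175 CpGs were lower and 140 higher at Div8pos than Div0, 1067 and 11 at Div8neg, and 533 and 6 at Div8pos against Div8neg. CpGs with 90 to 100% methylation at Div0 of host 196 went in host 197 from 95.8% at Div0 to 91.3% at Div8neg and 86.5% at Div8pos, those with 60 to 70% went from 67.7% to 60.6% and 54.0%, those with 20 to 30% from 21.1% to 20.9% and 17.9%, and those under 10% from 2.48% to 3.23% and 2.29%.

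Among families of genes that share the letters of their symbol, 275 with at least 8 measured members were compared with matched random lists at Div8pos against Div0. Odorant receptor genes (Olfr, 255 genes, mean difference -8.04 points against -9.74), vomeronasal receptor genes (Vmn, 153 genes, -8.09 against -9.92) and zinc finger genes (Zfp, 294 genes, -4.73 against -5.72) lost less than matched lists. Genes with symbols that begin with Pik (16 genes, -10.7 against -6.93) lost more. Each of these families had an adjusted permutation p of 0.0344. Before adjustment each was at the smallest p that 4000 random lists can give, so the value does not rank them. Random lists were not matched on position, so members that lie close together counted as independent, which can make p too small. The Pik family includes Pik3ip1, an inhibitor and not a kinase, which was among the genes with the largest losses at Div8neg. The family was not tested without it. At Div8pos against Div8neg the Olfr, Vmn and Zfp families again lost less (adjusted permutation p = 0.0458 each, again from the smallest possible p).

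Gains at Div8neg formed a small group beside the losses, with 11 regions. Among them, an intron of Ttc7b (chromosome 12, 101586626 to 101586869, 6 of 9 covered CpGs) was at 12.8% ± 1.07 at Div0, 34.5% ± 1.91 at Div8neg and 11.1% ± 1.05 at Div8pos. An intron of Kit, a growth factor receptor (chromosome 5, 76000700 to 76000844), was at 1.14% ± 0.0891, 30.5% ± 5.43 and 5.74% ± 2.97. An intergenic region assigned to the immediate early gene Fos (chromosome 12, 86855245 to 86855400) was at 14.3% ± 1.30, 49.5% ± 4.12 and 21.5% ± 1.19. It lay at least 40393 bp from the nearest start site. An exon and the 3′ UTR of Klf2, a regulator of lymphocyte migration (chromosome 8, 74844761 to 74844875, 3 of 11 covered CpGs), were at 16.5% ± 3.21, 28.9% ± 0.168 and 9.54% ± 2.14. Other regions stayed nearer their Div8neg level at Div8pos, with an exon of Stx11 (chromosome 10, 12661118 to 12661154) at 23.0% ± 0.811, 46.1% ± 3.35 and 41.3% ± 3.26, and a 5′ UTR and exon of Fam65c (chromosome 2, 167815193 to 167815205) at 3.74% ± 1.79, 24.2% ± 3.38 and 22.1% ± 1.20. Sorl1 (33.4% ± 0.898, 66.2% ± 5.14 and 49.9% ± 3.00) and Plscr3 (10.4% ± 5.94, 39.9% ± 1.25 and 27.7% ± 1.87) lay at Div8pos between their Div0 and Div8neg levels.

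The 204 CpGs that were higher at Div8neg than Div0 in host 197 were followed in host 196, where their mean was 11.9% at Div0, 13% at Div1, 16.3% at Div3, 18.2% at Div5, 25.2% at Div8neg and 14.5% at Div8pos. Incomplete bisulfite conversion of Div8neg is argued against, since CpGs under 5% at Div0 of the other host changed in host 196 by -0.0208 of the gain at these CpGs, and in host 197, where each of these CpGs was chosen for a gain of at least 20 points, by 0.724 points. Div8neg lay 10.7 points above Div8pos at these CpGs, as would be seen with a gain in CD138-negative cells of 8 or more divisions and also with DNA of other cells in that sort. These cannot be told apart, since low CpGs of B cell identity genes near a start site changed by 0.00371 of that gain but no table here gives their level in other cells. The 14 CpGs chosen for a gain in host 196 did not gain in host 197. Their mean there was 34.0% at Div0, 21.6% at Div8neg and 28.0% at Div8pos, with 14.3% of them higher at Div8neg than at Div0. Div8neg minus Div8pos there was -6.47 points, which goes against a gain in CD138-negative cells of both hosts at these CpGs. Few CpGs and 1 library per fraction bear on this.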
